A study of Sinopodophyllum hexandrum with 2 samples.

How the data were processed

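Small RNA libraries were made from total RNA of mature leaf with a NEBNext small RNA kit and sequenced single-end, per the labels' protocols. The submitters' processing notes name cutadapt, an adapter trimmer, without a version. The mapper, the miRNA predictor, the transcript set, the reference miRNA collection and any filter are not given in the sources used here. The organism's name was given as Sinopodophyllum hexandrum, and the 2 libraries were grouped as treated and control from their titles.

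The deposited count table held whole-number read counts per predicted miRNA locus, with 1 column per library, not normalized, and each locus was named by a transcript, a start, an end and a strand. Neither a genome nor the transcript sequences were used here, so positions are on the authors' transcripts, the table pairs these with no gene names or gene features, and whether they count from 0 or 1 is not stated. The deposited lists of conserved miRNAs held names and mature sequences and no abundance. The names carry prefixes of other plant species, such as osa for rice. The sequences may therefore be those of reference entries, and whether reads of this plant were identical to them is unknown. Related entries may be matched by the same reads, so numbers of sequences per family may follow the reference collection. Each list was assigned to the library whose code it bears, since that code stands in the sample title and heads the count column. The reads behind the lists and the total reads per library are unknown. The prediction sets in which a locus was searched for are unknown too, so a count of 0 may stand for no reads or for a locus that was not predicted in that library.

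For predicted loci, each count was divided by the library's total over all predicted loci (3785 and 13445 reads), and the treated to control ratio of these shares was taken with an exact conditional 95% interval (Clopper-Pearson). These totals hold part of each library and are not its depth. A locus was described as higher or lower where the ratio was at least 2-fold, the interval excluded 1 and at least 10 reads were summed over both libraries. A count of 0 was set to a floor of 3 reads per library and the fold was given as a bound, beside the exact two-sided 95% limit, which is less extreme. No test of the treatment was made, because there was 1 library per group. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The ratio procedure was tested on simulated data for the 117 entries at the real totals, with 40 entries changed 4-fold in each of 200 simulations. Counts were drawn at each entry's mean share of the 2 libraries, so no entry was absent from a library by design. The simulation therefore covers counting error, not the choice of scale or loci that were not predicted in a library. Entries with under 10 simulated reads summed over both libraries were left out. Of the entries measured, intervals held the true ratio in 96.5%. Among the changed entries measured, 77.9% were recovered and 0% had the wrong direction, and 1.20% of the unchanged entries measured met the criteria.

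Conserved families were taken from the number in each miRNA name. Lists were compared by family, by name and by exact mature sequence. The conserved comparison had been planned on read counts, and since the lists held none, ratios, list medians and a minimum of 10 reads could not be applied to them. In their place, the planned fallback of listed families was used. Of 8 family lists fixed before the data were examined (transcription factor, auxin signalling, copper, laccase, sulfate and phosphate, small RNA machinery, MYB and resistance-gene families), the number of listed families and sequences was counted. Sequences were also grouped by single linkage at an edit distance of at most 5, or at most 3. Shares carry exact binomial intervals, and listed sequences are not independent samples.

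The loci named were fixed by a rule set before the data were examined: the 5 with the most reads, and the 8 with the largest fold each way among those that met the criteria. Since transcripts carry no gene names, only a few loci of this rule are named and the others are given as counts and ranges. The locus on transcript_1351 was chosen after its values were seen. Families in 1 list only were named up to 15 per library in order of family number. Alternatives tried were other totals, the median of ratios, TMM factors, other minimums and summed overlapping loci. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, of which edgeR gave only the TMM factors.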

Results

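Small RNAs of mature leaves of Podophyllum hexandrum (also called Sinopodophyllum hexandrum), a medicinal herb known as a source of the lignan podophyllotoxin, were profiled by single-end sequencing. The series holds 2 libraries, 1 from a treated sample and 1 from a control sample. What the treatment was is not given in the sources used here. The stated purpose was the identification of miRNAs not annotated before, and the labels add the comparison of treated with control leaf. Read counts were examined for predicted miRNA loci, and lists of mature sequences without read counts for conserved miRNAs. The predicted loci held 3785 reads in the control library and 13445 in the treated library, 3.55 times as many. With 1 library per group, no difference below has a replicate check, and every interval covers counting error only and compares these libraries, not the conditions.

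Conserved miRNAs were listed for 39 families in the control library and 30 in the treated library. Of the 47 families in either list, 22 were in both, 17 were in the control list only and 8 were in the treated list only. The shared families included miR156 and miR157, families best known for targeting SPL transcription factor genes, miR398, which targets superoxide dismutase genes, miR408, which targets plantacyanin and laccase genes, and miR482, which targets NBS-LRR resistance genes. They also included miR535, miR827 and miR160, but the miR160 sequence in both lists was the reverse complement of the strand best known for targeting auxin response factor genes. The share of families in both lists was 46.8% (exact 95% interval 32.1% to 61.9%). At the level of names it was 44.8% (81 of 181), and at the level of distinct mature sequences 41.0% (50 of 122). A family outside a list was not listed for that library, and the depth behind the lists is unknown, so no level or fold can be given for any conserved miRNA.

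The families in the control list only included several with well known targets. These were miR166, which targets HD-ZIP III genes, miR319, which targets TCP genes, miR390, which directs the processing of TAS3 RNAs, miR396, which targets growth-regulating factor genes, and miR858, which targets MYB genes. Each was represented by 1 to 3 distinct sequences. The control list also had miR168, a family known for targeting AGO1, but its only sequence was of 24 nt and was not the strand that targets AGO1. The next families by number were miR894, miR1532, miR2640, miR3630, miR5075, miR5162, miR5383, miR7733 and miR8016, each with 1 sequence. The 8 families in the treated list only were miR531, miR902, miR1848, miR1887, miR2629, miR6260, miR8175 and miR9726, each with 1 sequence.

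**Figure D1:**
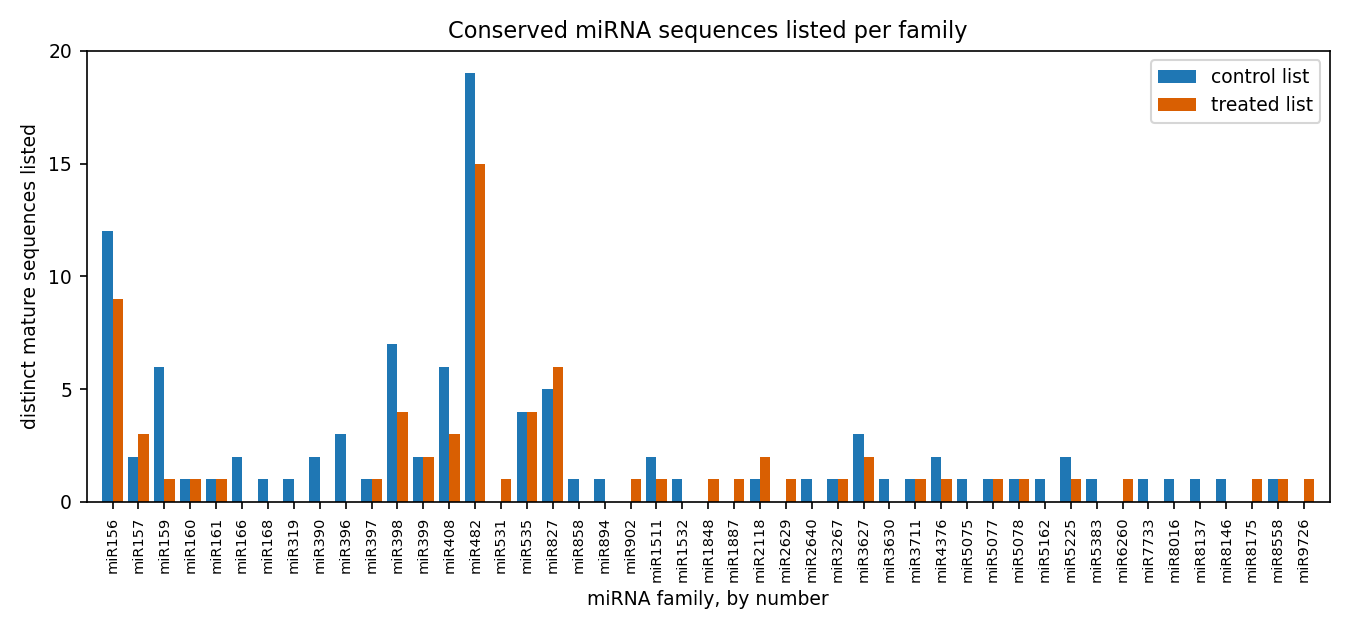
Number of distinct mature sequences listed per conserved miRNA family (vertical axis, count) for each of the 47 families by family number (horizontal axis), in the control list (blue bars) and the treated list (orange bars). miR482 has the most sequences in each list, 19 and 15, and miR159 has 6 in the control list against 1 in the treated list. Names are those of other plant species, so the counts may follow the number of related reference entries.

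Family lists fixed before the data were examined gave the following counts. Of the 16 families on the list of transcription factor regulators, 8 were listed. miR156, miR157, miR159 and miR160 were in both libraries, and miR166, miR319, miR396 and miR858 were in the control list only, with 28 distinct sequences in the control list and 14 in the treated list. Of these, 14 in the control list and 12 in the treated list were miR156 and miR157 sequences, all of the -3p arm, which is not the one best known for targeting SPL genes, and 2 of the 3 miR396 sequences were of the -3p arm too. Of 4 families on the list of MYB regulators, 3 were listed: miR159 was in both lists and miR319 and miR858 in the control list only. For this group the lists held 8 and 1 sequences with none identical, but all 6 miR159 sequences and the miR319 sequence of the control list lay within 5 edits of a sequence in the treated list. The auxin signalling list had miR160, by the opposite strand named above, in both libraries and miR390 in the control list only. Of 3 families on the small RNA machinery list, 1 was listed, miR168, in the control list only and by the 24-nt sequence named above. All 3 listed copper-responsive families (miR397, miR398 and miR408) were in both libraries, with 14 control sequences and 8 treated sequences, and 2 of these, miR397 and miR408, were those listed of the 3 laccase-targeting families, with 7 and 4 sequences. The sulfate and phosphate families miR399 and miR827 were in both, with 7 and 8 sequences. The resistance-gene families miR482 and miR2118 were in both, with 20 and 17 sequences, 15 of them shared. Some of the sequences counted in these groups were of the arm opposite to the others of their family. These were 1 of miR399 and 1 of miR482 in each list, and 1 of miR398 in the control list. None of the fixed-list families was in the treated list only.

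Families differed in how many of their listed sequences recurred. Several entries of a family differ by few bases and are named for different species. A sequence of this plant could match more than a single entry if mismatches were allowed, which is not stated. These counts may therefore follow the reference collection. All 4 miR535 sequences, a family related to miR156, were in both lists, and the sequence UGACAACGAGAGAGAGCACGC stood under 14 names in each. For miR482, 14 sequences were shared out of 19 in the control list and 15 in the treated list. For miR827, which is linked to phosphate status, 5 sequences were shared out of 5 and 6. For miR398, 3 sequences were shared out of 7 and 4, and for miR408, 3 out of 6 and 3. By contrast, miR159, miR397 and miR399 were in both lists without an identical sequence in common, though each of their sequences lay within 5 edits of one in the other list.

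The listed mature sequences were mainly of 21 and 22 nt and mainly began with U. Since their names carry prefixes of other plant species, these features describe the listed entries and not reads measured in this plant. The lists also share 50 sequences, so they are not separate sets. Of the 102 distinct sequences in the control list, 52.0% were of 21 nt and 35.3% of 22 nt. Of the 70 in the treated list, 48.6% were of 21 nt and 41.4% of 22 nt. A 5' U was present in 62.7% (exact 95% interval 52.6% to 72.1%) of the control sequences and 67.1% (54.9% to 77.9%) of the treated sequences, and these intervals overlapped. It was present in 74.0% (59.7% to 85.4%) of the 50 sequences in both lists, 27 of the 52 in the control list only and 10 of the 20 in the treated list only. The mean GC content was 52.8% ± 8.58 (SD over 102 sequences) in the control list and 52.3% ± 11.3 (SD over 70 sequences) in the treated list.

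The count table of predicted miRNAs had 117 entries. Of these, 116 were positions on 111 transcripts, given as in the authors' table with no gene names, and 1 carried the name of a rice miRNA, osa-miR5523, with 0 control and 2 treated reads. Only 9 loci (7.69%, exact 95% interval 3.58% to 14.1%) had reads in both libraries, 50 had control reads only and 58 had treated reads only. The share in both was 18.8% of the 48 loci with at least 10 reads summed over both libraries and 34.6% of the 26 loci with at least 50. The 9 shared loci held 69.3% (67.8% to 70.7%) of the control reads and 46.2% (45.3% to 47.0%) of the treated reads. Most loci were thinly covered: 69 had under 10 reads summed over both libraries, and 38 had 1 read. At the floor of 3 reads, a count of 0 allows a share of up to 0.0793% in the control library and 0.0223% in the treated library (exact two-sided 95% upper limits 0.0974% and 0.0274%), provided that the locus was searched for in that library, which the sources used here do not say.

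The most abundant locus in both libraries lay at positions 64 to 119 on the plus strand of transcript_2855. It had 1825 control reads, 48.2% of the library's predicted miRNA reads, and 4967 treated reads, 36.9%. The treated to control ratio of these shares was 0.766 (exact 95% interval 0.726 to 0.809), and it was 1.55 (1.47 to 1.64) when the libraries were scaled by TMM factors, so its direction depended on the scaling. The next 3 loci in total reads had treated reads only and together held 44.7% (43.8% to 45.5%) of the treated reads. The first of them lay on the minus strand of transcript_3916 (28 to 101), with 3220 treated reads, and the next on the plus strand of transcript_220 (882 to 930), with 1634. Against a floor of 3 reads per library, their shares were at least 302-fold and 153-fold higher in the treated library, and that of the last was at least 108-fold higher with 1154 reads. The exact 95% lower limits, which are less extreme, were 246-fold, 125-fold and 87.9-fold. All these bounds and limits hold only if the loci were searched for in the control library, which is unknown.

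**Figure D2:**
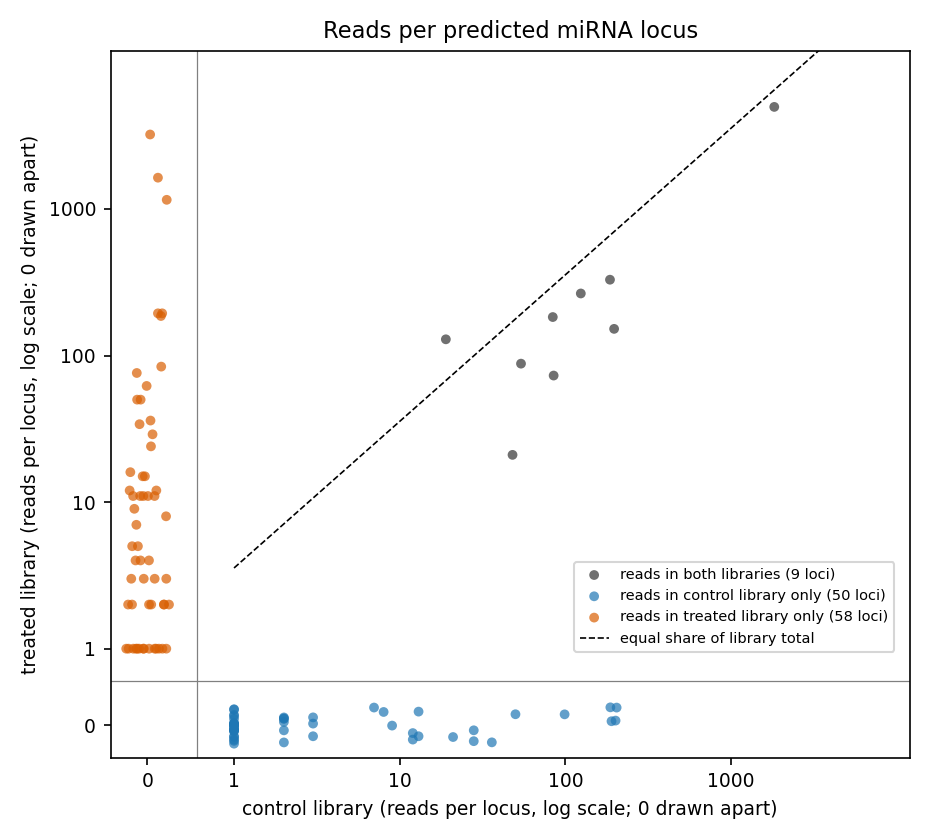
Reads per predicted miRNA locus in the control library (horizontal axis) and the treated library (vertical axis), both on log scales with counts of 0 drawn apart beyond the grey lines and spread slightly for visibility. Each point is 1 of 117 entries, coloured by the library or libraries in which it had reads, and the dashed line marks an equal share of both totals. Only 9 points lie off the 0 strips.

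Of 48 loci with at least 10 reads summed over both libraries, 15 had a share at least 2-fold higher in the treated library and 19 at least 2-fold lower, with counting intervals that excluded 1. The other 14 met neither criterion. With TMM factors or the median of ratios as the scale, 26 loci were higher and 17 lower, since these scales moved all log2 ratios up by 1.02 and 1.01. All 15 loci higher in the treated library by totals had 0 control reads, and 14 of the 19 lower ones had 0 treated reads. Because the totals differ, the floor weighs unevenly on these counts. Of the loci with at least 10 reads, 25 had treated reads only, and 15 of these met the criteria. All 14 with control reads only met them. The treated-only loci that met neither criterion had 11 to 16 reads. The counts of 15 and 19 therefore do not show that more loci were lower. A pair of loci on transcript_1829 that overlap by 46 bases counted once among the higher and once among the lower ones, and their summed reads, 50 control and 186 treated, gave a ratio of 1.05 (exact 95% interval 0.763 to 1.46). With overlapping loci summed, 15 loci were higher and 18 lower. Here transcript_1829 left the higher loci and a pair on transcript_1516 joined them. That pair overlaps by 22 bases with 11 treated reads at each locus, and whether the same reads were counted at both is unknown. Among the loci with control reads only, the most reads were at transcript_21648 (63 to 127, plus strand), with 204 control reads and a share at least 242-fold lower in the treated library against the same floor (exact 95% limit 195-fold). The next 3 had 187 to 201 reads, bounds of 221-fold to 238-fold against the floor and exact limits of 178-fold to 192-fold. With TMM factors these bounds were smaller, and that of transcript_21648 went from a log2 ratio of -7.92 to -6.90 (exact limit from -7.60 to -6.59). They hold only if the loci were searched for in the treated library, which is unknown.

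The 9 loci with reads in both libraries were the only ones with a measured ratio. As shares of all predicted miRNA reads, 8 were lower in the treated library and 1 was higher, with a median log2 ratio of -1.01. This split depends on the totals. Loci with treated reads only held 53.8% of the treated reads, and loci with control reads only held 30.7% of the control reads. That difference by itself lowers the shares of the 9 loci in the treated library. With TMM factors, 5 were above 1 and 4 below, but these factors rest on the same 9 loci, so a near-even split is largely built in. The lowest ratio, at a locus with 48 control and 21 treated reads, was 0.123 (exact 95% interval 0.0700 to 0.210). The next were 0.217 (0.175 to 0.270), with 197 and 152 reads, and 0.242 (0.174 to 0.335), with 85 and 73 reads. These 3 loci were at least 2-fold lower under all 5 scalings computed. However, all 5 were built from the predicted loci themselves, with a treated to control scale of 1.75 to 4.33. None used the library depth, which is unknown, so their agreement does not cover a scale outside this range. The locus on transcript_27234 (6 to 46, plus strand), the fifth in total reads, had 186 control and 329 treated reads and a ratio of 0.498 (0.415 to 0.599), which became 1.01 (0.840 to 1.21) with TMM factors. The highest ratio was that of transcript_1351 (413 to 468, plus strand), with 19 control and 129 treated reads. It was 1.91 (1.18 to 3.28) by totals and 3.87 (2.38 to 6.64) with TMM factors.

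**Figure D3:**
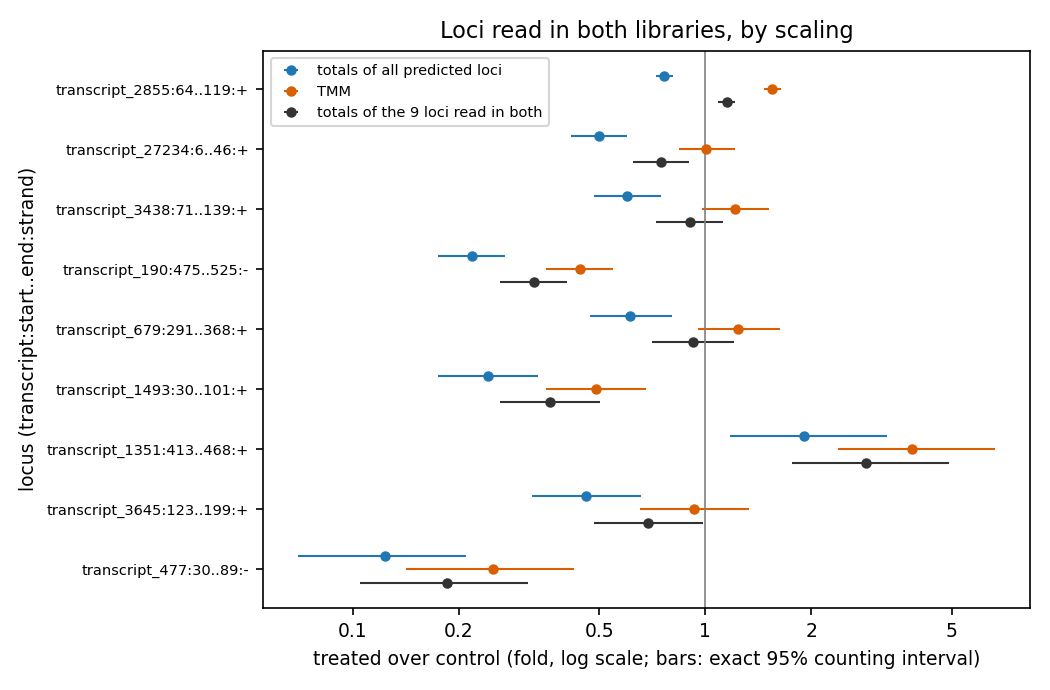
Treated to control ratio (horizontal axis, fold on a log scale) of the 9 loci with reads in both libraries (vertical axis), under scaling by the totals of all predicted loci (blue), by TMM factors (orange) and by the totals of the 9 loci alone (black). Points are ratios and bars are exact 95% counting intervals. The 3 loci with the lowest ratios lie below 1 under all 3 scalings, and the locus on transcript_2855 moves from 0.766 by totals to 1.55 with TMM factors.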

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

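The number of loci higher in the treated library was 15 with totals and 26 with the median of ratios and with TMM factors. Among the 9 loci with reads in both libraries, the median log2 ratio was -1.01 with totals. It was -1.29 without the most abundant locus in the total and -0.42 with the total of the 9 loci alone. It was 0.012 with TMM factors and 0 with the median of ratios, which sets it to 0 by construction. TMM factors rest on the same 9 loci, after trimming, so a value near 0 is largely built in there too. Of 18 loci that the naming rule selects, 10 moved beyond their counting interval or bound with TMM factors. Among these, the loci on transcript_2855 and transcript_27234 changed sign, from -0.384 to 0.634 and from -1.01 to 0.012 (log2). For the selected loci counted in 1 library only, the outcome was set by the upward shift. Those with treated reads only have no upper limit and could not move, and those with control reads only all moved. The count of 10 therefore does not measure how stable single loci were. With a minimum of 50 reads, 11 loci were lower against 19, since fewer loci were measured. Without the loci counted in 1 library only, 0 were higher and 5 lower. The other counts of higher and lower loci stayed within 1.5 times of those by totals, with 11 to 19 higher and 17 to 22 lower. The share of loci in both libraries was 7.69%, 18.8% with at least 10 reads and 34.6% with at least 50. Conserved list overlap stayed between 38.3% and 46.8% at the level of families, names, sequences and sequence groups. The share of 21-nt sequences in the control list was 52.0% per sequence and 64.5% per name. Totals of conserved plus predicted reads, and read minimums, list medians or read weights for conserved miRNAs, were not run, because the lists hold no counts. The total of the 9 shared loci, the left-out and summed loci, the minimums for the overlap, the sequence groups and the name weighting were chosen after seeing the data. Beyond how each alternative is built, the cause was not tested. No paired analysis was possible because there was 1 library per group.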

Other observations

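All tests in this part were chosen after the values were seen. Several listed families with different numbers had similar sequences. At an edit distance of at most 5, 6 groups joined 13 families, with miR5225 in 2 of the groups. They included miR156 with miR157 (17 sequences), miR159 with miR319 (8 sequences), miR482 with miR2118 and miR8558 (6 sequences) and miR3627 with miR4376 and miR5225 (5 sequences). Of 2440 shuffled versions of the listed sequences, 0.410% came this close to a listed sequence. All names of miR156 and miR157, 18 in the control list and 15 in the treated list, ended in -3p, the arm opposite to the strand best known for targeting SPL genes. The predicted loci had an end minus start of 40 to 88, with a median of 62, and 72 lay on the plus strand and 44 on the minus strand of their transcripts.

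Listed sequences of 24 nt, the length best known in plants for siRNAs that guide DNA methylation, were each in 1 list only. They were those of miR168, miR5162, miR5383, miR7733, miR8016 and miR8146 in the control list and of miR531 and miR2629 in the treated list. This is the length of entries named for other species, not a read length measured here. Each of these families had 1 listed sequence, so it could be in both lists only if that sequence recurred. Of the 25 families in 1 list only, 8 had a 24-nt sequence, against 0 of the 22 families in both (two-sided Fisher's exact p = 0.00446). Over sequences, the counts were 8 of 72 and 0 of 50 (two-sided Fisher's exact p = 0.0205). These p-values describe the counts that prompted the tests, so they are no separate evidence, and where the entries come from was not tested.

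Most predicted loci were counted in 1 library only. For 32 of the 108 such loci, the other library had 0 reads where an equal share of the totals gives at least 10, and 29 of these passed by the median of ratios too, which argues against sampling depth for those 29 as a set. For 33 others, all with treated reads only, the expected count by totals was under 3, so sampling depth cannot be told apart from absence. The remaining ones had expected counts of at least 3 and under 10, and sampling depth was not judged for them. A candidate explanation is separate prediction in each library: 2 of 3 pairs of overlapping loci held reads of opposite libraries at nearly the same place, in 1 pair with starts 2 bases apart and 50 control and 186 treated reads. For loci without such a partner this stays open, as does the treatment, since there was 1 library per group.

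Some loci had equal counts. Of those with at least 50 reads, 4 shared their count with another locus of the same library, a pair at 194 and a pair at 50 treated reads. Reads shared between near-identical transcripts could give such pairs. Chance stays open too, since 14.6% of 10000 smoothed draws of the counts had as many ties (95% quantile 4). The pair at 194, on transcript_1636 and transcript_25701, had an end minus start of 45 each. The pair at 50 had 50 and 46, and the draws did not use these lengths.

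Of the 100 names in 1 list only, 22% (exact 95% interval 14.3% to 31.4%) belonged to a sequence that the other list held under another name, which argues against naming as the whole source of the difference between the lists. The miR398 sequence UGUGUUCUCAGGUCGCCCCUG stood under 12 names in the control list and 1 in the treated list. For 40 of the 72 sequences in 1 list only, the other list held a sequence within 5 edits, so related reference sequences matched by the same reads may account for them, and without read counts this cannot be told apart from a difference between the libraries. The other 32 lay farther away, which argues against it for them. They included all sequences of miR166, miR168, miR390, miR396 and miR858.

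Of the families in 1 list only, 6 of 17 in the control list and 0 of 8 in the treated list belonged to the family lists fixed before the data were examined, and a difference was not shown (two-sided Fisher's exact p = 0.129). Of the 22 families in both lists, 11 belonged to them.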
